A study of Mus musculus with 18 samples.

How the data were processed

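The 18 samples fall into 8 groups: ∆Foxp3 and WT mice aged 3 weeks (V2 kit, 2 samples each), ∆Foxp3 mice aged 3 weeks, WT mice aged 9 weeks, sorted WT Treg and sorted WT Tconv cells (V3 kit, 2 samples each), and ∆Foxp3 and WT cells of mixed chimeras (V3 kit, 3 samples each). Per the labels, all mice were male and splenic TCRβ+ CD4+ cells were sorted, the chimera cells also by CD45.1 and CD45.2. Per the labels, the chimera recipients were 7 weeks old at transplant, received 1000 rad and marrow depleted of CD3+ cells, 50% from each donor, and were sampled 10 weeks later, which adds up to 17 weeks where the age label gives 16. Strain differs between groups: WT mice of the first experiment carried Foxp3-IRES-GFP, those of the second were also crossed to CD45.1, and ∆Foxp3 mice carried a YFP reporter at the ROSA locus. The labels state no separate animal for each sample outside the chimeras. There the 2 samples of each V3 group carry 1 hashtag in 2 channels and may be 1 mouse, so p-values may measure technical spread.

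The UMI counts per gene and cell were made by the authors with Cell Ranger 3.0.2 against mm10, per the submitters' processing notes, and deposited as 1 matrix of 26652 cells and 33006 genes, 17739 of them with a UMI. How reads of Foxp3, GFP, Cre and YFP were assigned, and whether the strand was used, is not given in the sources used here. In the deposited matrix the Foxp3 values are sums, of Foxp3 and GFP counts in all 14863 WT cells and of Foxp3 and Cre counts in all 11789 ∆Foxp3 cells. The Foxp3, GFP and Cre values given here are the separate deposited counts. The sum stayed in the tests of genes. It can therefore be among the genes called between ∆Foxp3 and WT cells, though it is built differently in each genotype. YFP counts were 0 in all cells. The percent of mitochondrial UMIs per cell is deposited by the authors and reached 15.0% at most. Per the file headers, the doublet score per cell comes from Scrublet. The score reached 0.293, and none of the deposited cells is called a doublet, so no cell was removed here. The fraction of reads in cells and the sequencing saturation of the V2 libraries are Cell Ranger summaries deposited by the authors. The matrix sum equals the deposited number of UMIs in 92.2% of cells, and falls short by at most 54 UMIs in the others. The deposited metadata give the V3 kit for all 26652 cells, while the labels give V2 for the first experiment; the labels and the lower depth of those cells were followed. Another 35 metadata columns were not used.

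Cells were grouped by the authors' annotation into Treg, activated Tconv and resting Tconv classes. Cells of the NKT cluster lie in the activated Tconv class and were counted there. Every sorted GFP+ cell is annotated as Treg, so the annotation is not independent of the sort. UMIs were summed over the cells of each sample, over all cells, Treg-annotated cells and Tconv cells, with at least 20 cells of a class per sample. Samples held 148 to 5271 cells and 955097 to 14887898 UMIs, and chi-square per degree of freedom between replicates was 2.15 to 12.6, where counting error alone gives 1. Sums were tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr with a minimum count of 10, quasi-likelihood F test), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no fold threshold. The 4 V2 libraries had a fit of their own, and the 14 V3 samples shared 1 fit. CPM were computed here from the sums, and log2 CPM used a prior count of 2. Shares of classes were tested with edgeR on numbers of cells per sample and by exact permutation. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for sums, shares and figures.

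Before the data were examined, the comparisons, tests, alternatives, the rule for named genes and 25 gene lists were fixed. The lists hold 435 members, of which 426 were matched by symbol, 6 by an older symbol and 3 not at all: Treg signature, genes known to be lower in Treg, naive and resting, activated and memory, Th1 and cytotoxic, Th2, Th17, Tfh, inhibitory receptors, cytokines, interferon response, proliferation, glycolysis, oxidative phosphorylation, cholesterol synthesis, IL-2 and STAT5 targets, homing receptors, immediate early genes, mitochondrially encoded transcripts, and markers of B, plasma, myeloid, CD8 T and NK, erythroid, and gamma delta and NKT cells. Several genes stand in more than 1 list. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over all lists and the 7 comparisons of all cells or the 6 within a class, and Foxp3 was left out of them. Named genes are the 10 with the highest and the 10 with the lowest fold change (5 and 5 within a class) among genes past the threshold with a mean of at least 20 CPM and no overlap between the samples compared, Foxp3, and up to 4 members per list with the lowest p. A gene with 0 counts in a group was set against a floor of 3 counts over the group, and one with 1 to 3 counts is given as a ratio with its 95% interval. Intervals and floors cover counting error only. Ifitm1 and Ifitm2, Serpina3f and Serpina3g, Gp49a and Lilrb4, Ccl3 and Ccl4, and H2-Q6 and H2-Q7 have near-identical copies and Gt(ROSA)26Sor is annotated as antisense, so the reads of each are uncertain in origin.

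Per the labels each chimera mouse had a hashtag of its own, and ∆Foxp3 and WT samples of the same number carry the same one. They were taken as 1 mouse in the replicate blocks only, while the main fits, permutations and splits did not use the pairing. The ∆Foxp3 and WT samples of each mouse lay in different 10x channels. Deviations of log2 CPM from the group mean correlated at only 0.082, -0.051 and 0.1 within the 3 pairs. In the V3 comparisons of ∆Foxp3 with WT mice, of Treg with Tconv cells and of chimera ∆Foxp3 with ∆Foxp3 mice the shared numbers mark the 10x channel, per the deposited batch names (correlations 0.352, 0.3, and 0.079 and 0.172). Blocks were fitted on the compared groups alone. Alternatives were DESeq2 1.42.0 (with its own filtering in place of filterByExpr), relative log expression scaling, no filter, each replicate left out, the same number of cells per sample, the compared groups alone, the channel as a covariate, replicate blocks, no cells with markers of other types or NKT annotation, estimated correlation and fry for lists, and limma for shares. Single cells were thinned to 1500 UMIs for shares of cells with a UMI. Gene positions are from GENCODE vM21 on GRCm38.

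The procedure was tested on simulated data, with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. For ∆Foxp3 against WT it recovered 64% and 95% of them in the V2 comparison, 65% and 91% in the V3 comparison and 82% and 98% in the chimeras. It recovered 56% and 88% for the interaction, 51% and 71% for Treg against Tconv, 77% and 92% for chimera WT against WT, and 80% and 93% for chimera ∆Foxp3 against ∆Foxp3. Within the Treg class it recovered 49% and 92%, 26% and 74%, and 48% and 81%, and within the Tconv class 71% and 91%, 63% and 93%, and 80% and 100%, in the V2, V3 and chimera comparisons. False calls made up 3.36% to 9.15% of the calls.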

Results

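RNA was measured in single CD4 T cells sorted from mouse spleen, with 10x Genomics kits that tag the end of each transcript and count it by its unique molecular identifier (UMI). The mice were WT males with a GFP reporter behind Foxp3, the gene of the transcription factor that defines regulatory T cells (Treg), or ∆Foxp3 males, whose Foxp3 allele is disrupted by EGFP and Cre. In the first experiment, run with the V2 kit, 3-week-old ∆Foxp3 mice gave 10430969 UMIs in 3290 cells (replicate A) and 4267372 UMIs in 1442 cells (replicate B). The 3-week-old WT mice of that experiment gave 14887898 UMIs in 5271 cells (A) and 11383384 UMIs in 3918 cells (B).

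The second experiment, run with the V3 kit, held 14 samples told apart by hashtag antibodies in 2 10x channels. The 3-week-old ∆Foxp3 mice gave 7192886 and 9438617 UMIs (1001 and 936 cells), and the 9-week-old WT mice gave 4364625 and 2402201 UMIs (814 and 352 cells). Irradiated recipients were given equal parts of WT and ∆Foxp3 marrow, and the cells of each origin were sorted 10 weeks later by CD45 alleles. The ∆Foxp3 cells of these mixed chimeras gave 11884169, 5997672 and 11406752 UMIs (2136, 909 and 2075 cells; replicates 1 to 3), and the WT cells 4695455, 9496000 and 5434171 UMIs (747, 1850 and 839 cells). Sorted GFP+ Treg cells of WT mice gave 1659790 and 1472737 UMIs (331 and 231 cells), and sorted GFP-negative conventional CD4 T cells (Tconv) 1935241 and 955097 UMIs (362 and 148 cells). Outside the chimeras the 2 samples of a V3 group carry the same hashtag in different channels, so whether they are 2 mice or 1 is not known. The median depth was 2774 to 3143 UMIs per cell with the V2 kit and 4731 to 8856.5 with the V3 kit.

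Foxp3 (chromosome X, 7573644 to 7595245, GRCm38) was read first, as the disrupted gene. Its own UMIs were found in the ∆Foxp3 samples too, at 2.11 and 2.34 CPM (UMIs scaled to the total of the sample) in the first experiment against 2.28 and 2.55 in WT. Where the counted end lies outside the disrupted part, Foxp3 UMIs check nothing, and how its reads were assigned is not given in the sources used here. In the second experiment Foxp3 reached 2.92 and 3.92 CPM in ∆Foxp3 mice against 0.917 and 3.75 CPM in 9-week-old WT mice. In the chimeras it reached 0.589, 1.50 and 0.789 CPM in ∆Foxp3 chimera cells against 8.09, 4.11 and 3.68 CPM in WT chimera cells. Sorted Treg cells held 28.9 and 25.1 CPM. A Foxp3 UMI was seen in 11.8% and 12.5% of sorted Treg cells (median depth 4731 and 5747 UMIs). It was seen in 0 of 362 and 0 of 148 sorted Tconv cells (median depth 5176 and 6402 UMIs), which allows up to 1.01% and 2.46% of cells with a UMI (exact binomial interval).

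Cre, which only the ∆Foxp3 allele carries, was counted in 12 and 17 UMIs in the V2 ∆Foxp3 samples, in 27 and 33 in the V3 ∆Foxp3 samples, and in 2, 0 and 3 in the ∆Foxp3 chimera samples. No Cre UMI was counted in any of the 11 WT samples, where 3 UMIs would have been 0.202 to 3.14 CPM. GFP UMIs reached 212 and 250 CPM in the V3 ∆Foxp3 mice, 64.3 and 101.5 CPM in the V2 ∆Foxp3 mice, and 80.1 and 109 CPM in sorted WT Treg cells. GFP stood at 3.96, 12.5 and 3.16 CPM in ∆Foxp3 chimera cells, below the 22.6, 17.8 and 18.8 CPM of WT chimera cells. A GFP UMI was seen in 40.4% and 40.8% of cells of the V3 ∆Foxp3 mice (median depth 6735 and 8856 UMIs), against 0.829% and 2.03% of sorted GFP-negative Tconv cells. With every cell thinned to 1500 UMIs the group means were 22.1% ± 0.243 and 0.338% ± 0.478 (SD, n = 2). Per cell class in those 2 samples, 35.7% and 31.7% of resting Tconv cells, 41.3% and 46.6% of activated Tconv cells and 67.7% and 60.6% of Treg-annotated cells held a GFP UMI.

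**Figure D1:**
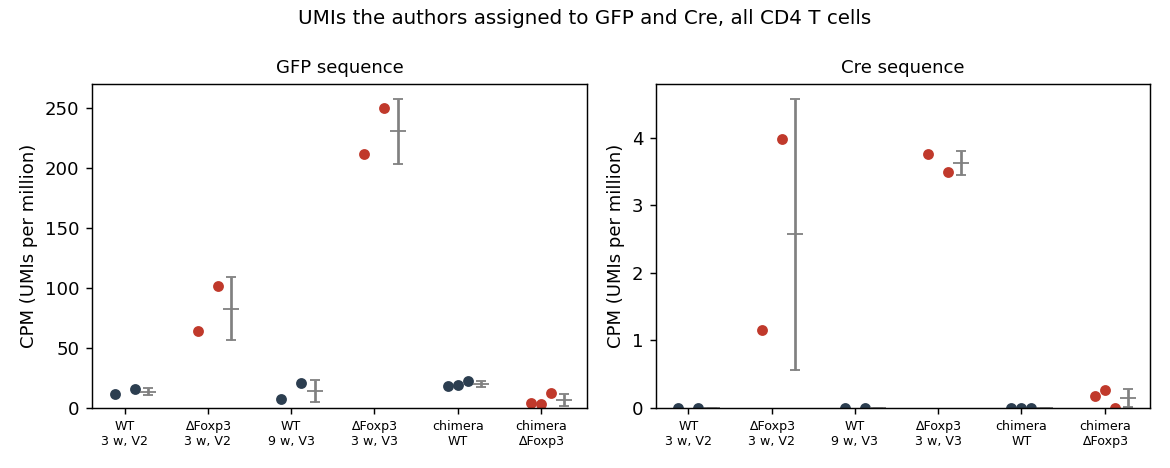
GFP and Cre CPM by group, 1 point per sample. GFP reached 212 and 250 CPM in the V3 ∆Foxp3 mice and 3.16 to 12.5 CPM in ∆Foxp3 chimera cells, and Cre was at 0 in the WT samples.

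The first question was how the authors' annotated classes, Treg, activated Tconv and resting Tconv, were shared out among all CD4 T cells. Some Treg clusters hold sorted Treg cells only, so Treg-annotated shares of unsorted samples may leave out cells of those kinds. The activated Tconv class includes the NKT cluster. That cluster held 3.33% of WT and 2.17% of ∆Foxp3 cells with the V2 kit, and 1.28% and 1.39% with the V3 kit. Activated Tconv cells rose from 11.8% ± 0.892 of WT cells to 30.0% ± 11.6 of ∆Foxp3 cells at 3 weeks with the V2 kit (SD, n = 2 per group; log2 fold change 1.34, SE 0.30, edgeR adjusted p 0.0127). With the V3 kit they rose from 17.3% ± 3.72 in 9-week-old WT mice to 46.7% ± 1.05 in 3-week-old ∆Foxp3 mice (log2 fold change 1.46, SE 0.37, edgeR adjusted p 0.00497). Resting Tconv cells fell from 76.4% ± 6.34 to 46.5% ± 1.44 with the V3 kit (log2 fold change -0.72, edgeR adjusted p 0.00159), and were 82.8% ± 1.05 of WT and 63.2% ± 13.1 of ∆Foxp3 cells with the V2 kit, which did not pass (log2 fold change -0.39, edgeR adjusted p 0.326). Treg-annotated cells made up 6.79% ± 1.48 of ∆Foxp3 cells and 5.35% ± 0.160 of WT cells with the V2 kit (edgeR adjusted p 0.326), and 6.77% ± 0.394 against 6.39% ± 2.61 with the V3 kit (edgeR adjusted p 0.688). A simulated 3-fold fall of this share was called in 27 of 50 V2 and 38 of 50 V3 sets, so a fall could be missed. With the V2 kit the resting Treg cluster held 1.72% of ∆Foxp3 and 4.27% of WT cells (edgeR adjusted p 0.0159). The activated Treg cluster held 4.42% and 1.08% (edgeR adjusted p 0.00367). Neither cluster passed with the V3 kit (edgeR adjusted p 0.291 and 0.372). In the chimeras the Treg-annotated share fell from 9.12% ± 0.569 of WT cells to 3.16% ± 1.45 of ∆Foxp3 cells (n = 3 per group; log2 fold change -1.61, SE 0.32, edgeR adjusted p 0.00136). Activated Tconv cells made up 16.3% ± 6.32 of ∆Foxp3 and 18.8% ± 2.24 of WT chimera cells (edgeR adjusted p 0.454).

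Exact two-sided permutation tests cannot pass in these designs: the smallest p is 0.333 for 2 against 2 samples, which both activated Tconv comparisons reached, and 0.1 for 3 against 3. The chimera Treg share reached 0.1 with the samples permuted freely, so that the mouse shared by a ∆Foxp3 and a WT sample was not used. The activated Tconv call of the first experiment was lost without WT replicate A (log2 fold change 1.26) or WT replicate B (1.42) and with limma on arcsine square roots of the shares (difference 0.225), and that of the second without 9-week-old WT replicate 1 (1.23). Chimera mouse 2 stood apart, with 8.47% of its ∆Foxp3 cells in the follicular helper (Tfh) cluster.

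**Figure D2:**
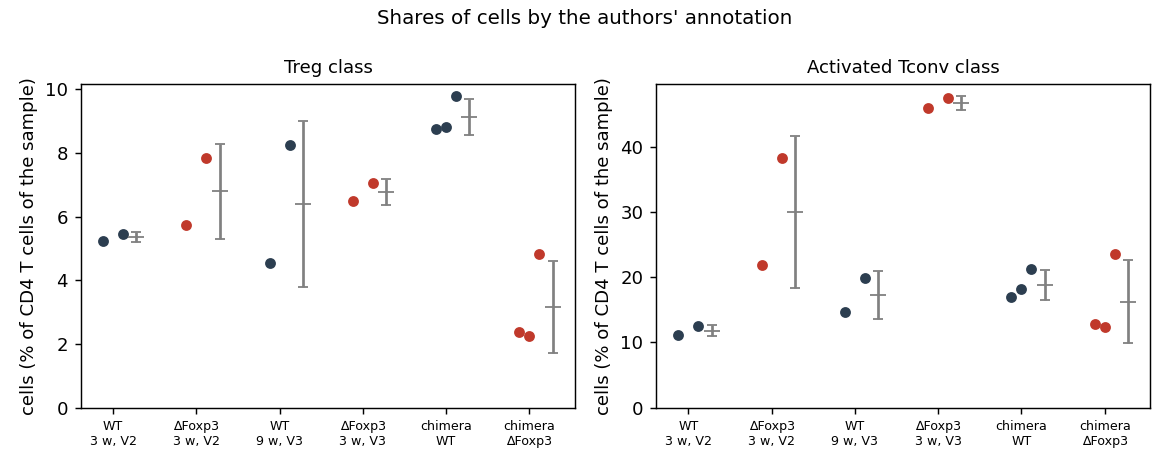
Percent of CD4 T cells annotated as Treg and as activated Tconv in each sample of 6 groups, with 1 point per sample and the group mean ± SD. The chimera ∆Foxp3 samples average 3.16% Treg against 9.12% in chimera WT, and activated Tconv cells average 30.0% and 46.7% in the 2 groups of ∆Foxp3 mice.

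Sorted WT Treg cells were compared with sorted WT Tconv cells to give the transcripts that mark Treg cells in these libraries (n = 2 per group). Of 10918 genes tested, 673 were higher and 656 lower in Treg cells (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Il2ra, the high-affinity IL-2 receptor chain, stood at 207 ± 52.4 CPM in Treg cells and 2.16 ± 3.05 CPM in Tconv cells (log2 fold change 7.09, SE 0.58, edgeR adjusted p 2.01e-06). Ikzf2, the Treg-associated transcription factor Helios, rose by 5.25 on the log2 scale (SE 0.76) and Ctla4, an inhibitory receptor, by 4.83 (SE 0.64), with edgeR adjusted p of 0.000327 and 0.000152. Lrrc32, which presents latent TGF-β on the Treg surface, was at least 79.1-fold higher against a floor of 3 counts over the Tconv group. Itgae, the αE integrin, had a ratio of 60.3 (95% counting interval 16.4 to 502).

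Among the 37 measured Treg signature genes 32 rose and 5 did not pass, and 35 rose when adjusted over the list alone. Their median log2 fold change was 3.99 (3.36 with undetected genes at their bounds, camera adjusted p 4.31e-21, adjusted p = 0.249 with an estimated correlation). The lowest transcripts in Treg cells were Pdlim4 (log2 fold change -4.80), Pde3b (-4.72), Dapl1 (-4.37; 21.4 ± 6.11 against 442 ± 38.6 CPM) and Igfbp4 (-3.05). Of 18 naive and resting T cell genes, among them Tcf7 (-2.15) and Lef1 (-1.95), 14 fell, 1 rose and 3 did not pass (15 and 2 adjusted over the list alone, camera adjusted p 1.58e-08, adjusted p = 0.324 with an estimated correlation). IL-2 and STAT5 target genes rose in 8 of 14 cases (8 rose and 1 fell adjusted over the list alone), including Cish (2.99) and Pim1 (1.77) (camera adjusted p 0.00174, adjusted p = 0.299 with an estimated correlation). Beside these, 12.1% and 19.0% of sorted Treg cells held markers of other cell types or an NKT annotation, against 3.59% and 6.08% of Tconv cells. Of 10 B cell markers 3 rose, among them Cd74 (2.28) (camera adjusted p 0.136, and 0.0163 with the shared channel as a block). Of 12 mitochondrially encoded transcripts, a sign of RNA quality, 10 fell (median log2 fold change -0.41, camera adjusted p 6.75e-06, adjusted p = 0.375 with an estimated correlation). Without Tconv replicate 1 there were 422 calls and without Treg replicate 2 there were 701.

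The comparison of ∆Foxp3 with WT mice at 3 weeks asked what changes in CD4 T cells when Foxp3 is disrupted throughout the animal (V2 kit, n = 2 per group). Of 10675 genes tested, 1535 rose and 1026 fell in ∆Foxp3 cells (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 387 and 40 of them by 4-fold or more. Ifitm1, an interferon-inducible membrane protein, was at least 455-fold higher, from 0 UMIs in WT. Among the other genes named by rule, rises were found in Ccl3, an inflammatory chemokine (log2 fold change 7.89), Gzma and Gzmb, cytotoxic proteases (5.19 and 5.06), and Lgals3, galectin-3 (5.61, SE 0.28, edgeR adjusted p 0.000309; 248 ± 82.6 against 5.05 ± 0.0373 CPM). Ctse, the protease cathepsin E, fell by 3.82 on the log2 scale (SE 0.11, edgeR adjusted p 9.85e-05; 12.4 ± 1.79 against 170 ± 5.49 CPM). Cd55, a complement-regulating surface protein, fell by 2.81 (SE 0.13, edgeR adjusted p 0.000302). Dapl1 (-1.98), Hsph1 (-1.75), Actn1 (-1.69), St8sia6 (-1.59) and Zbtb20 (-1.38) were also among the 10 largest falls.

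Grouped by list, 23 of 27 activated and memory T cell genes rose, 24 when adjusted over the list alone, among them Itgb1 (2.35), S100a4 (3.28) and S100a6 (2.79). Their median log2 fold change was 1.59 (camera adjusted p 1.17e-09, adjusted p = 0.434 with an estimated correlation). Th1 and cytotoxic genes rose in 14 of 18 cases (17 adjusted over the list alone), with Ifng, the Th1 cytokine, at 68.2 against 3.46 CPM (log2 fold change 4.22). The Th1 list median was 2.47 (camera adjusted p 6.28e-08, adjusted p = 0.408 with an estimated correlation). Proliferation genes rose in 21 of 26 cases (22 adjusted over the list alone), as in Birc5 (3.94), Ube2c (3.51) and Top2a (2.17) (median 2.24, camera adjusted p 1.82e-09, adjusted p = 0.408 with an estimated correlation). Among 31 interferon response genes 21 rose, 2 fell and 8 did not pass (22 and 3 adjusted over the list alone), Iigp1 from 22.0 to 268 CPM (3.61) and Gbp2 from 52.1 to 436 CPM (3.07), both interferon-inducible GTPases. The interferon list median was 0.97 (camera adjusted p 2.4e-06, adjusted p = 0.408 with an estimated correlation). The Treg signature rose in 24 of 35 genes and fell in 1 (26 and 1 adjusted over the list alone, median 1.20, camera adjusted p 1.04e-08, adjusted p = 0.408 with an estimated correlation), with Ctla4 at 1.20 and Nrp1 at 1.56. Naive and resting genes fell in 12 of 18 cases (14 fell and 1 rose adjusted over the list alone), Il7r by 0.71 on the log2 scale (median -0.56, camera adjusted p 1.97e-05, adjusted p = 0.434 with an estimated correlation). Genes known to be lower in Treg fell in 8 of 10 (9 over the list alone, median -0.68, camera adjusted p 0.000155, adjusted p = 0.408 with an estimated correlation).

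Tfh genes rose in 10 of 12 cases (10 rose and 1 fell adjusted over the list alone), among them Tox2 (3.39) and Pdcd1 (2.72) (camera adjusted p 7.57e-05, adjusted p = 0.324 with an estimated correlation). Th17 genes rose in 4 of 5 (5 over the list alone, camera adjusted p 0.0028, adjusted p = 0.364 with an estimated correlation). Inhibitory receptor genes rose in 7 of 13 cases and fell in 1 (8 and 1 adjusted over the list alone), Lag3 from 2.82 to 91.9 CPM (4.94) (camera adjusted p 0.000191, adjusted p = 0.408 with an estimated correlation). Cytokine genes rose in 7 of 13 (7 over the list alone, camera adjusted p 0.000315, adjusted p = 0.408 with an estimated correlation). IL-2 and STAT5 targets rose in 6 of 14, with 1 fall (10 and 1 adjusted over the list alone), as in Cish (2.20) and Socs1 (2.06) (camera adjusted p 0.00131, adjusted p = 0.324 with an estimated correlation). Glycolysis genes rose in 8 of 16 (9 over the list alone, median 0.25, camera adjusted p 0.0192, adjusted p = 0.364 with an estimated correlation). Cholesterol synthesis genes fell in 5 of 16 (5 over the list alone, median -0.23, camera adjusted p 0.00422, adjusted p = 0.408 with an estimated correlation). Oxidative phosphorylation genes rose in 7 of 22 (8 over the list alone, median 0.20, camera adjusted p 0.00796, adjusted p = 0.408 with an estimated correlation). That call was lost without ∆Foxp3 replicate A or WT replicate A (adjusted p up to 0.058). The lists of Th2 (4 of 8 rose), homing (7 rose and 3 fell of 17) and immediate early genes (7 rose and 2 fell of 15) did not pass (camera adjusted p 0.0658, 0.199 and 0.0773).

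Markers of other cells moved with these groups: myeloid markers rose in 3 of 11 cases (5 adjusted over the list alone, camera adjusted p 0.00631, adjusted p = 0.34 with an estimated correlation). B cell markers rose in 5 and fell in 3 of 10 (camera adjusted p 0.642). CD8 T and NK cell markers rose in 1 and fell in 1 of 7 (camera adjusted p 0.525), erythroid markers fell in 1 of 5 (camera adjusted p 0.936). The 1 measured plasma cell marker did not pass, and 1 of 2 gamma delta and NKT markers fell. Mitochondrially encoded transcripts fell in 7 of 12 (9 over the list alone, median -0.36, camera adjusted p 0.000268, adjusted p = 0.36 with an estimated correlation). The fraction of reads in cells was 0.597 and 0.534 in ∆Foxp3 against 0.791 and 0.795 in WT. Cells with markers of other types or an NKT annotation made up 30.2% of ∆Foxp3 replicate B and 5.87% to 9.01% of the other 3 samples. The number of calls was 3881 and 4046 without ∆Foxp3 replicate A or B, and 453 and 515 without WT replicate A or B.

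In the second experiment ∆Foxp3 mice aged 3 weeks were compared with WT mice aged 9 weeks, so that age and genotype change together (V3 kit, n = 2 per group). Of 10918 genes tested, 2416 rose and 2278 fell in ∆Foxp3 cells (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 2277 of the falls without the deposited Foxp3 sum. The 10 largest rises by the rule for named genes include Serpina3f, a serine protease inhibitor (log2 fold change 6.71, SE 0.45, edgeR adjusted p 3.4e-08), Lilrb4, an inhibitory immunoglobulin-like receptor (6.21), and Ifitm2 (5.27; 259 ± 3.6 against 7.49 ± 4.66 CPM), with Lgals3 (5.04) and Gzma (4.76). They also include Ccl1, a chemokine with 2 counts in WT, whose ratio was 190 (95% counting interval 52.4 to 1570). Dapl1 fell by 5.13 on the log2 scale (SE 0.17, edgeR adjusted p 3.58e-11; 11.2 ± 3.56 against 384 ± 34.1 CPM). Ctse fell by 4.07 (SE 0.17, edgeR adjusted p 4.5e-10; 9.25 ± 0.113 against 156 ± 7.92 CPM). Gt(ROSA)26Sor, the RNA of the locus that holds the reporter in ∆Foxp3 mice (chromosome 6, 113067428 to 113077333), fell by 5.03 (SE 0.16; 1.21 ± 0.0721 against 40.0 ± 0.767 CPM). Ccr7, a chemokine receptor of naive T cells, fell by 2.75.

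All 27 activated and memory T cell genes rose, as in Bhlhe40 (4.70), Id2 (2.80) and Vim (2.35) (27 over the list alone, median log2 fold change 2.32, camera adjusted p 9.45e-11, adjusted p = 0.338 with an estimated correlation). Naive and resting genes fell in 16 of 18 cases (16 over the list alone, median -1.90, camera adjusted p 3.36e-11, adjusted p = 0.299 with an estimated correlation). Th1 and cytotoxic genes rose in 16 of 18 (16 over the list alone), with Nkg7, a cytotoxic granule protein, higher by 3.29 (median 2.87, camera adjusted p 1.23e-06, adjusted p = 0.201 with an estimated correlation). Proliferation genes rose in 25 of 26 (26 over the list alone), as in Ccnb2 (3.53) (median 2.74, camera adjusted p 2.76e-06, adjusted p = 0.434 with an estimated correlation). Glycolysis genes rose in 15 of 17 (15 over the list alone), Tpi1 by 1.74 and Pfkp by 0.96 (camera adjusted p 1.75e-06, adjusted p = 0.324 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 16 (11 over the list alone), Idi1 by 2.10 and Fdps by 1.56 (median -1.15, camera adjusted p 2.55e-06, adjusted p = 0.201 with an estimated correlation). Of 32 interferon response genes 21 fell and 11 did not pass (21 fell and 1 rose adjusted over the list alone), among them Usp18 (-3.42) and Ifit1 (-3.11; 7.68 against 68.8 CPM), both type I interferon targets. The list had a median of -0.92 (camera adjusted p 3.33e-07, adjusted p = 0.387 with an estimated correlation).

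Th2 genes rose in 5 of 8 cases (5 over the list alone), including Il1rl1, the IL-33 receptor (3.86) (camera adjusted p 0.00653, adjusted p = 0.324 with an estimated correlation). Th17 genes rose in 4 of 6 and inhibitory receptor genes rose in 7 and fell in 1 of 13 (camera adjusted p 0.0772 and 0.0839, and 0.017 and 0.0233 with the shared channel as a block). The Treg signature rose in 20 and fell in 5 of 37 genes (the same counts adjusted over the list alone, camera adjusted p 0.0203, adjusted p = 0.626 with an estimated correlation), lost without WT replicate 1 (adjusted p 0.322). Myeloid markers rose in 8 and fell in 1 of 13 (camera adjusted p 0.0347, adjusted p = 0.408 with an estimated correlation), lost without WT replicate 1 or ∆Foxp3 replicate 2 (adjusted p up to 0.109). All 12 mitochondrially encoded transcripts fell (median -0.82, camera adjusted p 2.07e-09, adjusted p = 0.299 with an estimated correlation). B cell markers had a median of 0.21 and a mean of -0.08 (4 rose and 2 fell of 10, camera adjusted p 0.987). Without WT replicate 1 the number of calls was 2584, against 4694 with it.

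Between the 2 experiments, whose comparisons share no library, 10377 genes were tested in both, Foxp3 left out. Of these 1057 rose in both and 708 fell in both, where independent lists would share 323.7 and 218.3, and 50 moved in opposite directions where 541.5 would. Fold changes had a Pearson correlation of 0.733 and a Spearman correlation of 0.648 across genes, which are not independent replicates.

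In the mixed chimeras WT and ∆Foxp3 CD4 T cells shared the same mice. The comparison asked what the cells' own genotype changes in an animal that has WT Treg cells (n = 3 per group, ∆Foxp3 and WT cells of the same 3 mice). Here 23 of 10918 genes rose and 27 fell in ∆Foxp3 cells (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 6 and 8 of them by 4-fold or more. Without the deposited Foxp3 sum, which is built differently in each genotype, 26 fell. Ctse (chromosome 1, 131638306 to 131675505) fell by 2.93 on the log2 scale (SE 0.12, edgeR adjusted p 2.3e-09; 21.8 ± 6.03 against 160 ± 11 CPM). Il2ra fell by 2.05 (SE 0.27, edgeR adjusted p 0.00136; 7.38 against 28.2 CPM). Gt(ROSA)26Sor fell by 0.81 (SE 0.07), Rnaset2b, an RNA-degrading enzyme, by 0.80 and Cd55 by 0.69 (SE 0.09, edgeR adjusted p 0.00147). Tnfrsf9, the costimulatory receptor 4-1BB, fell by 1.73 (13.3 ± 3.54 against 42.0 ± 6.27 CPM, edgeR adjusted p 0.00846), Itgae by 2.38 and Gpr83, a Treg-enriched receptor, by 1.22. Treg-annotated cells made up 3.16% of ∆Foxp3 and 9.12% of WT chimera cells. Falls of Il2ra, Tnfrsf9, Itgae and Gpr83 over all cells therefore mix this share with any change within cells. Crip1, a small LIM-domain protein (chromosome 12, 113146316 to 113153879), rose by 1.77 (SE 0.13, edgeR adjusted p 1.62e-06; 879 ± 145 against 257 ± 28.1 CPM), and Ttc13 by 1.38 (SE 0.10, edgeR adjusted p 1.62e-06). Dapl1 rose by 0.67 in the chimera (415 ± 36 against 261 ± 21.9 CPM, edgeR adjusted p 0.0076).

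The Treg signature fell in 6 of 37 genes, and in 31 when adjusted over the list alone (median log2 fold change -1.14, camera adjusted p 4.48e-26, adjusted p = 0.201 with an estimated correlation). Over all cells this fall, too, mixes the smaller Treg-annotated share with any change within cells. IL-2 and STAT5 targets fell in 2 of 14 (6 over the list alone, camera adjusted p 0.000315, adjusted p = 0.249 with an estimated correlation). The proliferation list was lower (median -1.43, camera adjusted p 9.11e-10, adjusted p = 0.408 with an estimated correlation). In it 0 of 26 genes passed over all genes tested with edgeR or with DESeq2, 17 had an unadjusted p under 0.05, and 14 fell when adjusted over the list alone. The dividing cluster of activated Tconv cells held 1.10% of ∆Foxp3 and 1.39% of WT chimera cells (edgeR adjusted p 0.864). The lower proliferation list over all cells can likewise mix the smaller Treg-annotated share with any change within cells. Among activated and memory genes 1 of 27 rose, and 1 rose and 10 fell adjusted over the list alone (median -0.48, camera adjusted p 5.45e-05, adjusted p = 0.434 with an estimated correlation). The interferon response list had a median of -0.07 (camera adjusted p 0.237), and Th1 and cytotoxic genes a median of 0.01 and a mean of -0.22 (camera adjusted p 0.291). In these lists 0 genes passed with edgeR or DESeq2, and 2 of 32 and 4 of 18 had an unadjusted p under 0.05. Mitochondrially encoded transcripts rose in 1 of 12 cases and in 9 when adjusted over the list alone (median 0.19, camera adjusted p 6.79e-11, adjusted p = 0.299 with an estimated correlation).

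Erythroid markers fell in 1 of 5 cases, Hba-a2, and in 4 when adjusted over the list alone (camera adjusted p 0.0111, adjusted p = 0.408 with an estimated correlation; 0.279 with the mouse as a block). That call was lost without chimera WT replicate 2 or 3 or ∆Foxp3 replicate 2 (adjusted p up to 0.423). Genes known to be lower in Treg rose in 2 and fell in 1 of 10 (camera adjusted p 0.00685, adjusted p = 0.434 with an estimated correlation), lost without chimera WT replicate 1 (adjusted p 0.0674). The number of calls was 16, 203 and 22 without ∆Foxp3 replicate 1, 2 or 3, and 27, 88 and 25 without WT replicate 1, 2 or 3. Fitted on the 6 chimera samples alone, 146 genes passed without and 37 with the mouse as a block. Calls were lost for Tnfrsf9 (-1.57, -1.69), Itgae (-2.15, -2.37) and Hba-a2 (-5.24, -6.67) without ∆Foxp3 replicate 1 or 3, for Gpr83 (-1.14) without ∆Foxp3 replicate 1, and for Dapl1 (0.62, 0.60) without ∆Foxp3 or WT replicate 1. With the same number of cells per sample they were lost for Il2ra (-2.99), Tnfrsf9 (-1.43), Gpr83 (-1.09), Gt(ROSA)26Sor (-0.60), Rnaset2b (-0.75) and Cd55 (-0.72).

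**Figure D3:**
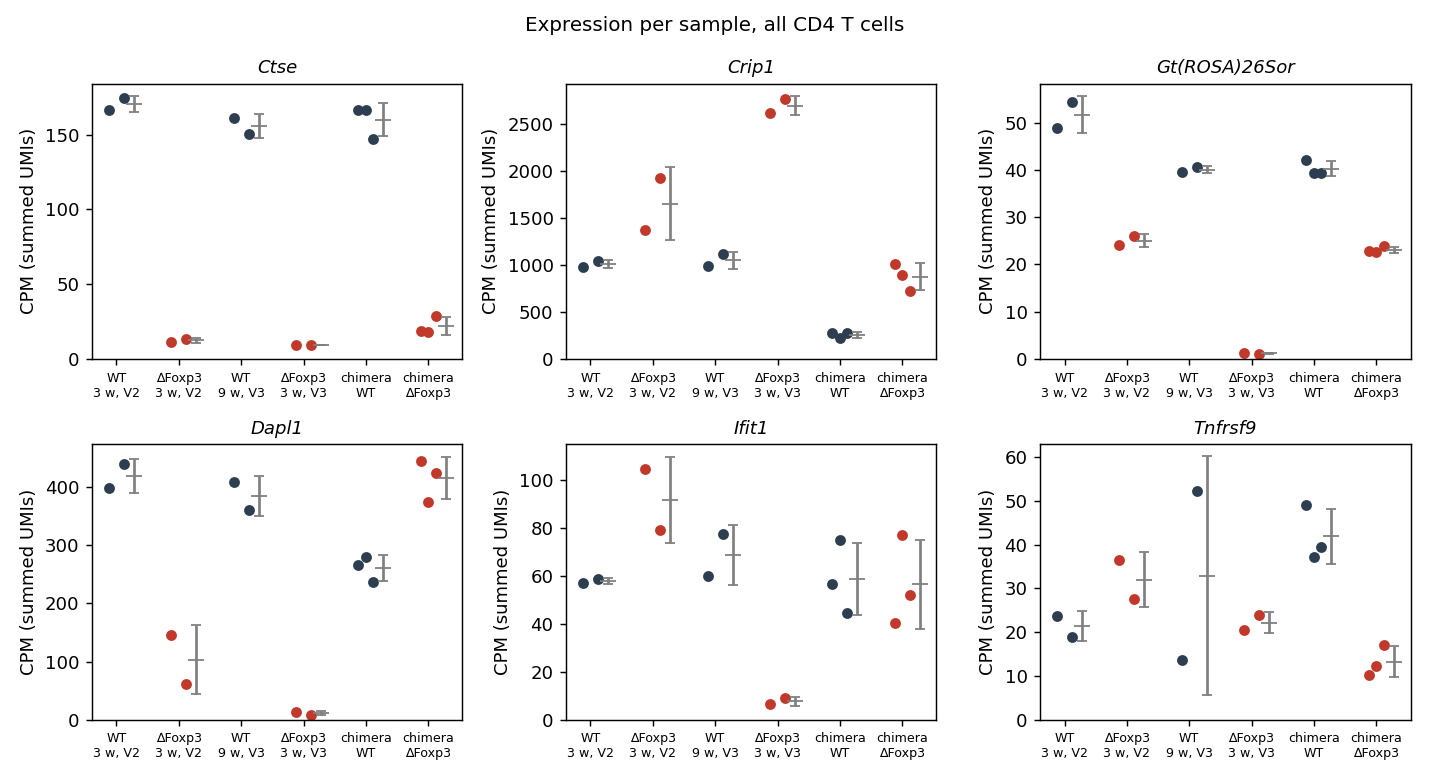
CPM of Ctse, Crip1, Gt(ROSA)26Sor, Dapl1, Ifit1 and Tnfrsf9 by group, 1 point per sample. Ctse averages 21.8 CPM in ∆Foxp3 and 160 CPM in WT chimera cells, while Dapl1 averages 415 and 261 CPM there and 11.2 CPM in the V3 ∆Foxp3 mice.

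The effect of ∆Foxp3 outside the chimera was tested against that inside it by an interaction term in the V3 samples (n = 2 per group outside, 3 inside). Outside, age differs between the genotypes and inside it does not. The ∆Foxp3 cells outside and inside may also differ genetically, since Gt(ROSA)26Sor stood at 1.257 and 1.155 CPM outside and at 22.6 to 23.8 CPM inside. In all 4020 genes differed, 2042 with a higher and 1978 with a lower effect outside (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The difference was largest upward in Ccna2, a cyclin of DNA replication (5.98, SE 1.06, edgeR adjusted p 0.000464), Lgals3 (5.83), Gzmb (5.73) and Mki67, a marker of dividing cells (5.07). It was largest downward in Dapl1 (-5.80, SE 0.20, edgeR adjusted p 1.17e-10), Pdlim4 (-4.70), St8sia6 (-4.64) and Igfbp4 (-3.94). Proliferation genes had a higher effect outside in 25 of 26 cases (25 over the list alone, median 4.00, camera adjusted p 4.25e-08, adjusted p = 0.408 with an estimated correlation). Activated and memory genes had a higher effect outside in 26 of 27 (26 over the list alone, camera adjusted p 8.28e-11, adjusted p = 0.338 with an estimated correlation). The Treg signature differed in 26 of 37 genes, 25 of them with a higher effect outside (26 higher and 2 lower adjusted over the list alone, camera adjusted p 1.58e-06, adjusted p = 0.408 with an estimated correlation). Interferon response genes had a lower effect outside in 21 of 32 (21 lower and 2 higher adjusted over the list alone, camera adjusted p 6.63e-06, adjusted p = 0.408 with an estimated correlation). All 12 mitochondrially encoded transcripts had a lower effect outside (median -1.02, camera adjusted p 8.28e-11, adjusted p = 0.299 with an estimated correlation). Without 9-week-old WT replicate 1 there were 2447 calls.

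**Figure D4:**
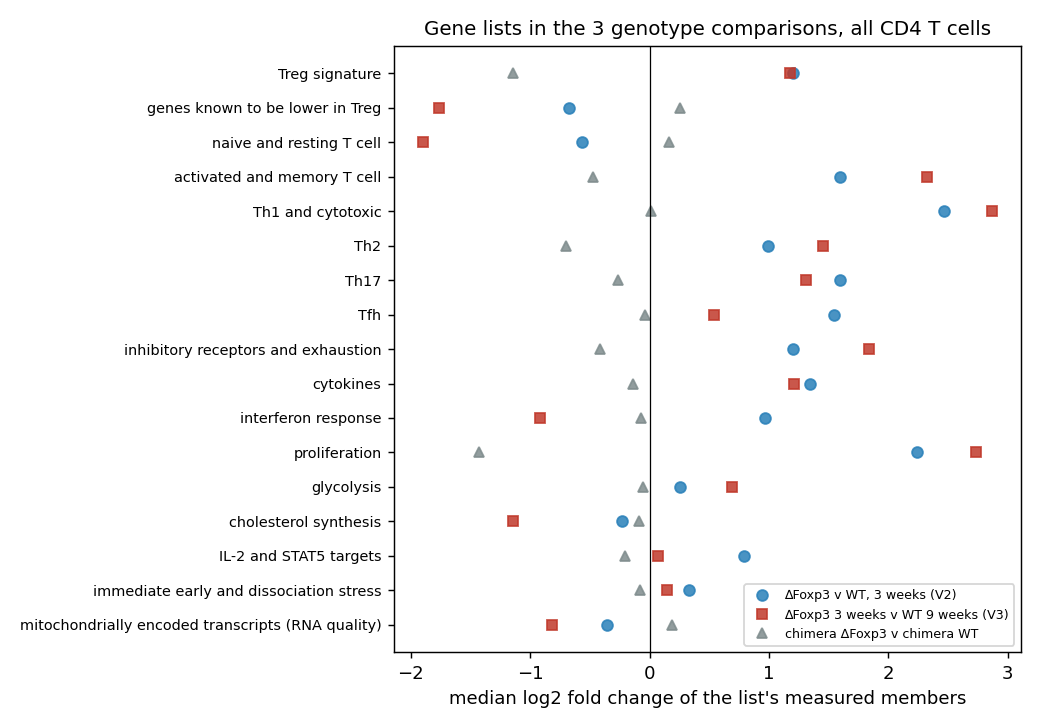
Median log2 fold change (∆Foxp3 against WT) of 17 gene lists in the V2, V3 and chimera comparisons, 1 point per list and comparison. The proliferation medians are 2.24, 2.74 and -1.43, and the interferon response medians 0.97, -0.92 and -0.07.

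Within the Treg-annotated class the question was what a cell that still resembles a Treg cell expresses without FOXP3. In the first experiment (n = 2 per group) 469 of 5492 genes rose and 428 fell in ∆Foxp3 cells. The authors placed 79.8% of WT Treg-annotated cells in the resting Treg cluster and 63.8% of ∆Foxp3 ones in the activated Treg cluster. Ccl5, a chemokine of effector cells, stood at 11240 against 245 CPM (log2 fold change 5.52, SE 0.17, edgeR adjusted p 1.7e-15), Gzmb at 297 against 7.98 CPM (5.16) and Nkg7 rose by 4.60. Il2ra fell by 2.44 (37.2 against 213 CPM, edgeR adjusted p 8.67e-08), Gpr83 by 1.90, Id3, a repressor of E proteins, by 2.95 and Ctse by 3.51. All 14 measured Th1 and cytotoxic genes rose (14 over the list alone, median 5.34, or 4.70 with undetected genes at their bounds, camera adjusted p 3.57e-17, adjusted p = 0.284 with an estimated correlation). Of 26 activated and memory genes 19 rose (20 over the list alone, camera adjusted p 1.32e-13, adjusted p = 0.308 with an estimated correlation). The Treg signature had a median of -0.12 and a mean of 0.12, with 6 of 30 genes higher and 9 lower (camera adjusted p 0.861). Mitochondrially encoded transcripts fell in 8 of 11 (10 over the list alone, camera adjusted p 0.00108, adjusted p = 0.336 with an estimated correlation). The number of calls was 550 without WT replicate A and 527 without WT replicate B, against 897.

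With the V3 kit (n = 2 per group, 3 against 9 weeks) the class held only 65 and 66 ∆Foxp3 cells and 37 and 29 WT cells. Of 6136 genes 221 rose and 214 fell (213 without the deposited Foxp3 sum) in Treg-annotated ∆Foxp3 cells. Of these cells 64.9% ± 3.94 lay in the activated Treg cluster. In WT replicates 1 and 2 the activated cluster held 35.1% and 55.2% of Treg-annotated cells. Nkg7 stood at 846 against 34.3 CPM (log2 fold change 4.63, SE 0.40, edgeR adjusted p 1.15e-09), Ccl5 rose by 4.56 and Id2 by 3.16. Tnfrsf9 fell by 3.89 (15.5 ± 11.9 against 252 ± 103 CPM, edgeR adjusted p 3.52e-08), Lrrc32 by 4.05, Il2ra by 2.37 and Id3 by 3.33. Th1 and cytotoxic genes rose in 9 of 12 (12 over the list alone, camera adjusted p 9.32e-10, adjusted p = 0.266 with an estimated correlation). Naive and resting genes fell in 7 and rose in 1 of 18 (10 and 1 over the list alone, camera adjusted p 7.97e-06, adjusted p = 0.356 with an estimated correlation). Cholesterol synthesis genes fell in 4 of 13 (5 over the list alone, camera adjusted p 5.41e-06, adjusted p = 0.266 with an estimated correlation). Interferon response genes fell in 4 of 26 (10 fell and 1 rose over the list alone, median -0.61, camera adjusted p 0.0035, adjusted p = 0.336 with an estimated correlation). Mitochondrially encoded transcripts fell in 8 of 12 (11 over the list alone, camera adjusted p 8.73e-08, adjusted p = 0.284 with an estimated correlation). The Treg signature fell in 9 and rose in 1 of 33 (14 and 5 over the list alone, camera adjusted p 0.00366, adjusted p = 0.471 with an estimated correlation), lost without WT replicate 2 (adjusted p 0.11). The number of calls was 208 without WT replicate 1 and 250 without ∆Foxp3 replicate 2, against 435.

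Treg-annotated cells of the chimeras (n = 3 per group) differed in 22 genes, 11 higher and 11 lower in ∆Foxp3 cells (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The class held 51, 44 and 47 ∆Foxp3 cells and 73, 162 and 74 WT cells (replicates 1 to 3). Without the deposited Foxp3 sum 10 genes were lower. With the mouse as a block 58 genes passed, 20 higher and 38 lower. The activated Treg cluster held 49.2% ± 1.34 of WT ones and 52.5% ± 9.93 of ∆Foxp3 ones, with 63.6% in ∆Foxp3 replicate 2. Tnfsf8, the CD30 ligand, rose by 2.01 (SE 0.26, edgeR adjusted p 4.53e-05; 119 ± 16.7 against 29.0 ± 1.14 CPM). Tnfrsf9 fell by 1.92 (SE 0.26, edgeR adjusted p 4.53e-05; 68.9 ± 24.4 against 255 ± 53 CPM), Ctse by 1.64 and Il2ra by 1.41 (SE 0.23, edgeR adjusted p 0.00106; 90.8 against 242 CPM). The Treg signature fell in 5 of 33 genes (13 over the list alone, median -0.53, camera adjusted p 2.05e-07, adjusted p = 0.342 with an estimated correlation). IL-2 and STAT5 targets fell in 2 of 12 (4 over the list alone, camera adjusted p 1.05e-05, adjusted p = 0.266 with an estimated correlation). Genes known to be lower in Treg rose in 3 and fell in 1 of 9 (6 and 1 over the list alone, camera adjusted p 0.00214, adjusted p = 0.393 with an estimated correlation). The number of calls was 5, 35 and 9 without ∆Foxp3 replicate 1, 2 or 3, and 8 without WT replicate 1 or 2. Between the first and second experiments 123 genes rose and 113 fell in both Treg-annotated comparisons, where independent lists would share 16.3 and 15, and 3 moved in opposite directions.

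Within Tconv cells the same comparisons gave 1461 higher and 947 lower genes in the V2 experiment, 2502 and 2208 in the V3 experiment, and 15 and 8 in the chimeras (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without the deposited Foxp3 sum 7 genes were lower in the chimeras. In the V2 Tconv cells Ctse fell by 3.84 (SE 0.12, edgeR adjusted p 7.78e-05) and Ccl3 rose by 7.74, and in the V3 ones Dapl1 fell by 5.16 and Lilrb4 rose by 6.34. The Treg signature rose in 25 of 35 genes in the V2 Tconv cells (27 over the list alone, median 1.69, camera adjusted p 3.98e-12, adjusted p = 0.397 with an estimated correlation). It rose in 23 and fell in 3 of 36 in the V3 ones (24 and 3 over the list alone, median 1.61, camera adjusted p 0.00121, adjusted p = 0.475 with an estimated correlation). In chimera Tconv cells it fell in 2 of 36 (22 over the list alone, median -0.92, camera adjusted p 1.18e-15, adjusted p = 0.284 with an estimated correlation). These cells held Foxp3 at 0.465 ± 0.0925 CPM in ∆Foxp3 and 2.48 ± 1.71 CPM in WT, so Treg cells left in the class stay open as a source of the list's fall, as for its called gene Klrg1 (ratio of fold changes in resting to all Tconv cells 0.202). There Ctse fell by 3.01 (SE 0.12, edgeR adjusted p 5.47e-09), Gt(ROSA)26Sor by 0.85, Rnaset2b by 0.79 and Cd55 by 0.68, while Crip1 rose by 1.77 (SE 0.11, edgeR adjusted p 1.14e-06) and Ttc13 by 1.37. The number of calls was 3889, 406 and 543 in V2 Tconv cells without ∆Foxp3 replicate B, WT replicate A or WT replicate B, and 2612 in V3 ones without WT replicate 1. In chimera Tconv cells fitted alone 69 genes passed without and 20 with the mouse as a block. With all V3 samples in the fit there were 74 calls without WT replicate 2 and 91 without ∆Foxp3 replicate 2.

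WT cells of the chimera were set against those of intact 9-week-old WT mice (n = 3 against 2), where transplantation, the mixed environment and age (16 against 9 weeks per the labels) change together. Of 10918 genes 8 rose and 12 fell in the chimera (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Crip1 fell by 2.03 (SE 0.14, edgeR adjusted p 1.57e-06; 257 ± 28.1 against 1052 ± 88.3 CPM), leaving chimera WT cells below both groups they were compared with. H2-Q7, a nonclassical MHC gene with close paralogs, rose by 0.96 (SE 0.08, edgeR adjusted p 2.17e-05; 671 ± 27.1 against 344 ± 16 CPM). Mitochondrially encoded transcripts fell in 6 of 12 (9 over the list alone, median -0.38, camera adjusted p 1.22e-17, adjusted p = 0.201 with an estimated correlation). The Treg signature passed the set test (median 0.54, camera adjusted p 6.75e-06, adjusted p = 0.408 with an estimated correlation). Of its 37 genes 0 passed with edgeR or DESeq2 and 5 had an unadjusted p under 0.05. The call was lost without WT replicate 1 (adjusted p 0.771), where the number of genes called was 9.

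∆Foxp3 cells of the chimera were set against those of intact ∆Foxp3 mice (n = 3 against 2), so that age, 16 against 3 weeks, changes together with the environment. RNA of the reporter locus, Gt(ROSA)26Sor, stood at 22.8, 23.8 and 22.6 CPM in the chimera and at 1.257 and 1.155 CPM in the ∆Foxp3 mice. The 2 sources of ∆Foxp3 cells may therefore differ genetically as well. In the chimera 2893 genes rose and 3000 fell (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Dapl1 rose from 11.2 ± 3.56 to 415 ± 36 CPM (log2 fold change 5.24, SE 0.17, edgeR adjusted p 1.53e-11), with Pdlim4 (4.46), St8sia6 (4.44), Igfbp4 (4.08) and Il6ra, an IL-6 receptor chain (3.64). Gzmb fell from 265 ± 32.6 to 4.90 ± 2.19 CPM (-5.70), Ccl4 by 6.77 and Lgals3 by 5.58. All 27 activated and memory genes and all 26 proliferation genes fell (27 and 26 over the list alone, camera adjusted p 6.21e-12 and 3.32e-08, adjusted p = 0.324 and 0.408 with an estimated correlation). Naive and resting genes rose in 15 of 18 (15 over the list alone, camera adjusted p 8.28e-11, adjusted p = 0.299 with an estimated correlation). Cholesterol synthesis genes rose in 15 of 16 (15 over the list alone, camera adjusted p 5.46e-07, adjusted p = 0.201 with an estimated correlation). Interferon response genes rose in 21 and fell in 2 of 32 (21 and 2 over the list alone, camera adjusted p 1.37e-05, adjusted p = 0.408 with an estimated correlation). The share of Treg-annotated cells was 3.16% ± 1.45 against 6.77% ± 0.394 (log2 fold change -1.18, edgeR adjusted p 0.00745), a call lost with the shared channel as a block (-0.997) and with limma. Myeloid markers fell in 9 and rose in 1 of 13 (camera adjusted p 0.00631, adjusted p = 0.364 with an estimated correlation), and all 12 mitochondrially encoded transcripts rose (median 0.71, camera adjusted p 9.33e-08, adjusted p = 0.324 with an estimated correlation).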

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

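The tests of the ROSA locus, of the V2 libraries for free RNA (by class and in resting cells) and for GFP over Cre, and of the called Treg signature genes in resting cells, and the 3 counts of splits, were chosen after the result was seen, and the other tests before.

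GFP UMIs, which the comparisons of genes use only within the Foxp3 sum of WT cells, averaged 71.55 CPM in Tconv cells of the V2 ∆Foxp3 mice. They averaged 221.6 CPM in those of the V3 ∆Foxp3 mice, where the highest WT sample held 14.9 CPM. In V3 replicates 1 and 2 GFP UMIs per cell were 4.025 times (95% counting interval 3.38 to 4.83) and 7.19 times (6.15 to 8.44) higher in the deepest than in the shallowest cells. Marker genes of other cells had upper limits of 3.35 and 4.02. This argued against free RNA taken up in droplets as the whole source in replicate 2, but could not decide for replicate 1, where the limits almost meet. Cells with the most marker UMIs were left out for the markers only. GFP UMIs also clumped more than counting intervals assume, with 40.4% and 40.8% of cells holding 1 against 78.2% and 92.0% at random. Cell classes were not separated in this test. In the V2 libraries free RNA was argued against for activated Tconv and Treg-annotated cells. At 1500 UMIs per cell these held a GFP UMI at least 2.732 times (interval 1.95 to 3.83) as often as resting Tconv cells, against an upper limit of at most 1.26 for the markers. Free RNA stays open for resting Tconv cells. There the deepest cells held 0.5821 times (0.382 to 0.877) the GFP UMIs of the shallowest in 1 library, below the markers (1.24 to 1.57), and the intervals overlap in the other. Over all cells of V2 replicates A and B the ratios by depth, for which no prediction was set, were 1.75 (1.39 to 2.22) and 2.08 (1.57 to 2.785). They overlapped those of the markers (upper limits 1.68 and 2.02). Transcripts of the ∆Foxp3 allele remain a candidate source: GFP over Cre was 1.205 times (interval 0.359 to 3.21) that of the ∆Foxp3 chimera cells in the V2 mice, under the 5 times set as the limit, and 2.048 times (0.633 to 5.15) in the V3 mice, with only 5 Cre UMIs in the chimera. YFP transcripts of the ROSA reporter counted as GFP stay open as well, since the Gt(ROSA)26Sor fold change was lower by -3.978 on the log2 scale in the V3 than in the V2 comparison, but the V2 one differed from that in the chimera by -0.24 (SE 0.127) while GFP was far lower in the chimera (3.16 to 12.5 CPM in all cells).

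The genes that differ between ∆Foxp3 and WT Tconv cells of the chimera lie near each other more often than random genes: 8 pairs within 5 Mb, against a median of 1 and a 95% limit of 3 in 10000 random sets (p 2e-04, smallest possible 1e-04). Ctse, Cd55 and Mfsd4 on chromosome 1, Tagap1 and Rnaset2b on chromosome 17, and Wnt5b, Klrg1, Nrip2 and Clec2i on chromosome 6, which also holds Gt(ROSA)26Sor, are among them, so chromosomal segments of other strain origin may account for part of the calls. A difference between the 10x channels was argued against, since 100% of the 22 genes (Foxp3 left out) kept their call and sign with the channel as a covariate. Treg cells left among the activated Tconv cells were argued against for most of the genes. The median ratio of fold changes in resting to all Tconv cells was 0.963, and 18 of 20 measured genes were called in resting cells. Such Treg cells stay open for Klrg1 (ratio 0.202, from -2.59 to -0.52) and Gm15987 (2.60 to 0.83), and for Itgae and Gm21464, which were not measured in resting cells. The ratio cannot decide for Treg cells left in the resting clusters, which would be in both sets. Resting cells also made up most of the class, at 80.6% of all ∆Foxp3 and 72.1% of all WT chimera cells. An effect of the ∆Foxp3 genotype on these genes stays open, as does the strain of each line.

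The interferon response list was higher in ∆Foxp3 mice in the V2 comparison and lower in the V3 comparison, a difference in medians of 1.889 on the log2 scale that was not tested. Shares of the clusters named for Irf7 were argued against, since without them the medians were 1.12 and -0.72. A mix of resting and activated cells was argued against as the whole cause, with 1.26 and -0.739 in resting Tconv cells, though in activated Tconv cells the V2 rise was absent (median -0.06, 6 genes higher and 7 lower of 27) and the V3 median was -1.07. Cells of other types were argued against, with 1.03 and -0.975 without them. Within the V3 experiment the list's mean was 4.16 and 4.11 log2 CPM in the ∆Foxp3 mice, below the 5.02 to 5.68 of all other samples, WT and chimera alike. The 9-week-old WT mice thus did not stand out from the other samples of that experiment. All of those were older than the ∆Foxp3 mice, and WT mice of the same age as the ∆Foxp3 mice were not among them. Low values of the ∆Foxp3 genotype therefore cannot be told from higher values in all older animals. Age of the WT mice, kit, experiment, strain and the 2 sets of ∆Foxp3 mice change together between the 2 comparisons and cannot be told apart.

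The ∆Foxp3 effect outside and inside the chimera differed in 4020 genes by the interaction test. For the chimera comparisons, the 10 splits of the 6 samples, made without regard to the shared mice, are too few for a share under 0.05. In each case 1 of 10 splits, the real one, gave as many genes. It gave 50 genes in all cells (highest other split 0), 22 in Treg-annotated cells (highest other 4) and 23 in Tconv cells (highest other 0). Without the deposited Foxp3 sum, which is built differently in each genotype, the real split gave 49, 21 and 22 genes.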

How the results depend on the processing

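All alternatives were planned. Relative log expression scaling changed none of 1234 named-gene results, and of all 14530 tries on named genes 13473 kept direction and side of the threshold, 420 gained a call, 632 lost it and 5 reversed. For list results these numbers were 1938, 93, 298 and 1 of 2330, and for class shares 89 kept, 5 gained and 8 lost of 102. The cause of the changes below was not tested, and a group left with 1 sample is assumed to vary like the others. Counting only cells with at least 1000 UMIs removes none (fewest 1542) and tests nothing.

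Without 1 library the calls ranged from 453 to 4046 (V2), 2584 to 4177 (V3), 16 to 203 (chimera), 2447 to 4123 (interaction), 422 to 1093 (Treg against Tconv), 9 to 20 (chimera WT against WT) and 4354 to 5782 (chimera ∆Foxp3 against ∆Foxp3). Within Treg they ranged from 527 to 906, 208 to 339 and 5 to 35, and within Tconv from 406 to 3889, 2612 to 4270 and 16 to 91 (V2, V3, chimera). Log2 fold changes of shares ranged from 0.893 to 1.703, 1.231 to 1.674 and -0.529 to -0.065 for activated Tconv, -0.62 to -0.194, -0.796 to -0.627 and 0.119 to 0.225 for resting Tconv, and 0.107 to 0.555, -0.283 to 0.573 and -1.944 to -1.415 for Treg. Resting Tconv gained a call without either V2 ∆Foxp3 replicate or chimera ∆Foxp3 replicate 2, activated Tconv without that chimera replicate, and Treg without V2 ∆Foxp3 replicate A. Without V2 ∆Foxp3 replicate B, Hbb-bs (-0.289) and Hbb-bt (-0.331) reversed in all cells, Hbb-bs in Treg (-0.736), and Hbb-bs (-0.262) and Hba-a2 (-0.524) in Tconv. Without replicate A they were 2.021 (Hbb-bs), 1.417 (Treg), 2.059 and 1.673 (Tconv).

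DESeq2, which also replaced the low-count filter by its own (15656 V2 and 17269 V3 genes entered, all cells), gave 1460 (V2), 139 (chimera) and 32 calls (chimera WT against WT), 271, 275 and 12 within Treg, and 1322 (V2) and 123 (chimera) within Tconv. The same number of cells per sample gave 1785 (V3), 12 (chimera), 1299 (interaction), 779 (Treg against Tconv), 11 (chimera WT against WT) and 2359 (chimera ∆Foxp3 against ∆Foxp3), 480, 275 and 9 within Treg, and 2067 (V3) and 9 (chimera) within Tconv. Without the filter there were 558 (chimera), 131 (chimera WT against WT), 58 (Treg, chimera) and 449 (Tconv, chimera). In the chimera the channel as a covariate gave 236 and 164 calls (all, Tconv) and the compared groups alone 146 and 69. With a replicate block there were 68 calls in chimera WT against WT, where samples share only a number (correlations -0.352 and -0.306), and 58 within Treg of the chimera. In chimera ∆Foxp3 against ∆Foxp3, where numbers 1 and 2 share a channel, the block ended the share calls at -1.428, 0.745 and -0.997 (activated, resting, Treg). The block also ended 14 named-gene calls of 1154 and changed the calls of lists not reported above, such as chimera oxidative phosphorylation (adjusted p 0.163) and homing genes (0.194). It moved no other count of changed genes by over 1.5 times from the reported one, but against fits of the compared groups alone it moved those of the chimera from 146 to 37 (all) and 69 to 20 (Tconv). Limma on shares ended the calls of activated Tconv (V2, 0.225) and Treg (chimera ∆Foxp3 against ∆Foxp3, -0.087).

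With an estimated correlation 0 lists passed in any of the 13 comparisons. Fry called 3 (chimera), 3 (chimera WT against WT), 1 (Treg, chimera), 10 (Tconv, V2) and 2 lists (Tconv, chimera), and reversed the V3 B cell markers (adjusted p 0.0268). Shared calls at adjusted p under 0.01 and at 50 CPM or more were 559 and 542 (V2 and V3), 5 and 6 (V2 and chimera), and 9 and 9 (V3 and chimera), within Tconv 531 and 511, 5 and 2, and 6 and 4, and within Treg 144, 4 and 4 at 0.01. Foxp3 in Treg-annotated cells alone was 10.1 and 27.5 CPM (V2 ∆Foxp3, WT), 17.2 and 13.5 (V3 ∆Foxp3, WT), and 16.9 and 36.8 (chimera ∆Foxp3, WT). Thinned to 1500 UMIs, 0.39% and 0.406% (V2 ∆Foxp3, WT), 0.684% (V3 ∆Foxp3), 0.185% and 0.97% (chimera ∆Foxp3, WT) and 3.91% of sorted Treg cells held a Foxp3 UMI, so depth limits these shares.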

Other observations

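The deposited clusters describe further cell types. In the V2 experiment Tfh cells made up 4.70% of ∆Foxp3 and 0.904% of WT cells (edgeR adjusted p 0.00367), and Th1 cells 6.50% and 2.72% (edgeR adjusted p 0.0184). In the V3 experiment neither passed, with 4.98% and 3.11% Tfh cells (edgeR adjusted p 0.444) and 4.13% and 4.32% Th1 cells (edgeR adjusted p 0.795), while 1 activated Tconv cluster made up 17.7% ± 1.93 of ∆Foxp3 and 0.733% ± 0.168 of WT cells. Sorted WT Treg cells were 37.2% resting Treg, and 19.9%, 13.6% and 3.35% lay in the furtive, tissue-like and dividing Treg clusters. No cell of any other group was placed in the furtive, tissue-like or dividing Treg clusters, so Treg-annotated shares of unsorted samples may leave out such cells. A Treg cluster called type A held 9.80% of V2 ∆Foxp3 Treg-annotated cells, but 1 of 131 such cells in the V3 ∆Foxp3 samples and 0 of 142 in ∆Foxp3 chimera cells.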
